A study of Homo sapiens with 6 samples.

How the data were processed

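RNA from MCF-10F cells, a human breast epithelial line described by the submitters as normal-like and negative for the estrogen receptor alpha and the progesterone receptor, was hybridised to 6 Affymetrix arrays. Per the labels, 2 arrays carried RNA from cells kept in the vehicle dimethyl sulfoxide (DMSO), 2 from cells given bisphenol A (BPA, a plasticiser with weak estrogenic activity) at 10 µM and 2 from cells given BPA at 1 µM. Per the series' design text, exposure lasted 2 weeks with fresh medium each day, the vehicle was 0.284% DMSO, and cells of both BPA doses were recovered after an invasion assay and grown for 6 passages. The labels do not say whether the arrayed BPA cells are those recovered cells or cells taken before the assay, and whether the vehicle cells passed through the same steps is not given in the sources used here. Biotin-labelled cRNA was made from 6 µg of total RNA, per the labels' protocols. The labels name Trizol for the RNA extraction and the design text names a Qiagen kit.

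The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes. By its standard definition RMA corrects background, quantile-normalises the arrays and summarises the probes of a probe set, but the version and options used are not given in the sources used here. RMA values carry no detection call, so a low log2 value has no stated background limit and a fold change against a group near the bottom of the scale is compressed. The table held no missing value. Array medians ran from 6.21 to 6.29 and standard deviations from 2.29 to 2.36, with the widest spread on replicate 1 of the 10 µM group. Precision is limited by the number of arrays, 2 in each group. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

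Probe sets were named from the platform annotation. Of the probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 were not listed. Among those with 1 symbol, 41037 were matched by gene identifier to a RefSeq gene table of assembly GRCh38.p14, which served for current symbols, gene lengths and the order of neighbouring genes. Each gene was represented by the probe set with the highest mean log2 value over the 6 arrays, which left 19775 genes, of which 10523 had more than 1 probe set. Probe sets with several symbols or none (13522 together) were tested apart and are not named. Some genes are not analysed here.

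Genes were tested with limma 3.58.1 in R 4.3.3. A model with a mean for each of the 3 groups was fitted to all 6 arrays with lmFit, and eBayes without a trend and without robust estimation moderated the variances (prior degrees of freedom 7.73, residual 3). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were each dose with DMSO and the higher dose with the lower. The SE given with a log2 change is limma's moderated SE of the difference, and the median SE was 0.0989. These choices, the gene lists and the alternatives, except where stated, were made before the data were examined.

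The 53 gene lists covered DNA repair pathways, the cell cycle, stress and metabolic programmes, inflammation, epithelial and mesenchymal genes, signalling targets and markers of other cell types, plus the union of the repair lists. They named 820 distinct genes, of which 741 were tested. The union leaves out the 6 repair genes that the study is known to have reported from these samples, which form a list of their own. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and the adjusted p covers 159 tests (53 lists in 3 comparisons). With the estimated correlation no list was called in any comparison, and the lowest adjusted p was 0.164. That test rests on the 3 residual degrees of freedom, which leaves it little power. The lack of a call there is therefore not by itself evidence against a list. It also uses a correlation well above the preset 0.01 for many lists. The estimate was 0.146 for the repair union, 0.183 for replication, 0.284 for homologous recombination and 0.502 for splicing factors. For other lists it was lower, such as -0.0103 for interferon-stimulated genes. Where the estimate is higher, the preset p-value may be far too small. For each list the numbers of genes called over all genes tested and adjusted over the list alone were recorded. The median, the mean and the test of a list differed in sign for 15 list results, all with an adjusted p above 0.05.

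Genes named in the text follow a fixed rule. For each dose against DMSO these are the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap between groups, every tested gene of the lists taken from the study, and up to 4 members of each list described, called ones first and then by p. Between the doses the rule takes the 5 largest in each direction and the same list members. Pseudogenes and non-coding RNAs were named where the rule reached them.

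The code was tested on simulated arrays with known changes. In the simulated comparison of 10 µM BPA with DMSO over 19775 genes, 92.5% of genes with a log2 change of 0.5 were recovered, and 100% of those with a change of 1 and 100% of those with a change of 2, with 13 false calls. A list of 60 genes shifted by 0.5 gave a median of 0.47. Because both doses share the 2 DMSO arrays, the agreement of the doses was set beside 100 simulations of unchanged groups sharing such controls. The agreement was also computed with a separate DMSO array for each dose, in both assignments of the 2 arrays, which was added after the data were seen and leaves 1 control array per dose.

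The alternatives were the replicate number as a block, a fit to the compared groups alone, quantile normalization of the deposited values, equal array medians, only genes in the upper part of the expression range, eBayes with a trend and robust estimation, the mean of all probe sets of a gene, the exclusion of probe sets ending in _x_at or _s_at (which can bind several transcripts), each array left out in turn, an added 2-fold threshold, and, for the repair list, an estimated correlation and the removal of cell cycle genes. The cell cycle genes removed from the repair list were LIG1, PCNA, FEN1 and RPA2, its only members that are also in the cell cycle lists. A block with the replicate numbers of the 10 µM group crossed was added after the data were seen. With 2 arrays in each group, tests for outlying arrays and counts of other splits of the samples do not apply.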

Results

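Gene expression was measured on 6 arrays of MCF-10F breast epithelial cells, with 2 arrays each for the vehicle DMSO, BPA at 10 µM and BPA at 1 µM. From the log2 RMA values 19775 genes were tested. Replicate arrays correlated at r = 0.997 (DMSO), 0.997 (10 µM) and 0.998 (1 µM) across probe sets, and arrays of different groups at 0.982 to 0.994. The first principal component held 67.9% of the variance and separated the 2 DMSO arrays from the 4 BPA arrays, and the second held 20.8% and separated the doses. The series asks, by its title, whether BPA raises the expression of DNA repair genes in these cells.

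At 10 µM BPA, lists of DNA repair, DNA replication and mitosis genes were called higher than in DMSO. Genes of sterol synthesis had the highest median of all lists. Lists of interferon-stimulated genes and histone genes were called lower. With an estimated correlation no list was called in any comparison (lowest adjusted p = 0.164). With 3 residual degrees of freedom that test has little power. Of 19775 genes, 6178 were called, 3414 higher and 2764 lower. The share of higher genes was 55.3%, but 48.4% after repeated quantile normalization and 63.1% with equal array medians, so the balance depends on scaling. At least 2-fold changes were seen in 762 of them (354 higher, 408 lower). The fixed union of repair lists held 119 measured genes, of which 61 rose, 6 fell and the rest were not called, with a median log2 change of 0.33. Its adjusted p was 1.58e-09 with the preset correlation and the adjusted p = 0.344 with an estimated correlation. Adjusted over the list alone, 67 rose and 10 fell.

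Among the 6 repair genes that the study is known to have reported, 3 were tested here. BRCA1, which directs repair by homologous recombination, rose by 0.78 ± 0.09 on the log2 scale (SE, n = 2 arrays per group), or 1.72-fold, from 9.59 ± 0.07 to 10.37 ± 0.08 (SD, n = 2; adjusted p = 7.65e-05). BARD1, its partner in a ubiquitin ligase, rose by 0.75 ± 0.10 (adjusted p = 0.000214), and BRCC3, a deubiquitinase of a BRCA1 complex, rose by 0.56 ± 0.09 (adjusted p = 0.000531). All 3 also passed adjusted over the list alone, and the list's adjusted p was 0.00517 (adjusted p = 0.251 with an estimated correlation). BRCA1 and BRCC3 were read from probe sets ending in _s_at and _x_at. Without such probe sets the list was not called (adjusted p = 0.115). Its median of 0.75 there was the value of BARD1, so it does not show that the rises of BRCA1 and BRCC3 held. Among the more highly expressed genes the list was not called either (adjusted p = 0.0504). Its median of 0.75 is fixed there, since that choice alters no log2 change. Because the study chose these genes on these samples, the count of 3 rises is not independent evidence of their direction.

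Each repair pathway was also tested as a list of its own at 10 µM, without a test between pathways. In the homologous recombination list 14 of 25 genes rose and 1 fell (median 0.37, adjusted p = 3.65e-05, adjusted p = 0.404 with an estimated correlation), with the translocase gene RAD54L up by 1.02 and the helicase genes BLM and BRIP1 up by 0.98 and 0.89. Checkpoint genes rose in 11 of 16 cases with none lower (median 0.46, adjusted p = 1.73e-05, adjusted p = 0.328 with an estimated correlation), among them CHEK1, a kinase that halts the cycle after replication stress, at 1.17, the fork protection gene TIMELESS at 0.86 and ATR at 0.70. All 8 mismatch repair genes rose (median 0.50, adjusted p = 0.000123, adjusted p = 0.257 with an estimated correlation), including EXO1 by 0.81 and LIG1 by 0.70. End joining (7 of 12 higher, 1 lower, median 0.39, adjusted p = 0.0102) included the DNA end binding subunits XRCC5 (0.59) and XRCC6 (0.48), and translesion synthesis (7 of 12 higher, none lower, median 0.37, adjusted p = 0.00497) included REV3L (0.99). Estimating the correlation gave adjusted p = 0.408 and adjusted p = 0.53. Among the more highly expressed genes both calls were lost (adjusted p = 0.118 and 0.137) with medians of 0.42 and 0.35. In base excision repair 9 of 19 genes rose and 1 fell (median 0.19, adjusted p = 0.0258, adjusted p = 0.352 with an estimated correlation): LIG3 rose by 0.80 and PARP1 by 0.85, while the gap-filling polymerase POLB fell by 0.79. In the Fanconi anaemia list 3 of 12 rose (median 0.19, adjusted p = 0.0247, adjusted p = 0.281 with an estimated correlation), with FANCI at 1.07. Nucleotide excision repair was not called (6 of 21 higher, 3 lower, adjusted p = 0.136). The base excision and Fanconi calls were lost among the more highly expressed genes (medians 0.19 and 0.21, adjusted p = 0.274 and 0.231), without probe sets ending in _x_at or _s_at (medians 0.06 and 0.15, adjusted p = 0.154 and 0.171) and after repeated quantile normalization (medians 0.13 and 0.12, adjusted p = 0.0661 for both).

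The cell cycle lists had higher medians than the repair union at 10 µM. In the replication list 31 of 33 genes rose and none fell (median 0.70, adjusted p = 1.18e-17, adjusted p = 0.22 with an estimated correlation), including the polymerase epsilon subunit POLE2 at 1.82 and the origin recognition genes ORC1 (1.20) and ORC6 (1.06). In the mitosis list 34 of 35 rose and 1 fell (median 0.83, adjusted p = 6.98e-19, adjusted p = 0.22 with an estimated correlation), with the spindle motor KIF11 at 1.48, the proliferation marker MKI67 at 1.42 and ASPM at 1.53. The G1/S list had 13 of 17 higher and 2 lower (median 0.64, adjusted p = 7.28e-06, adjusted p = 0.251 with an estimated correlation). Targets of p53 fell in 15 of 23 cases with 1 higher (median -0.45, adjusted p = 1.06e-05, adjusted p = 0.255 with an estimated correlation), including the cyclin-dependent kinase inhibitor CDKN1A at -1.12 ± 0.09 and TP53INP1 at -1.41.

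**Figure D1:**
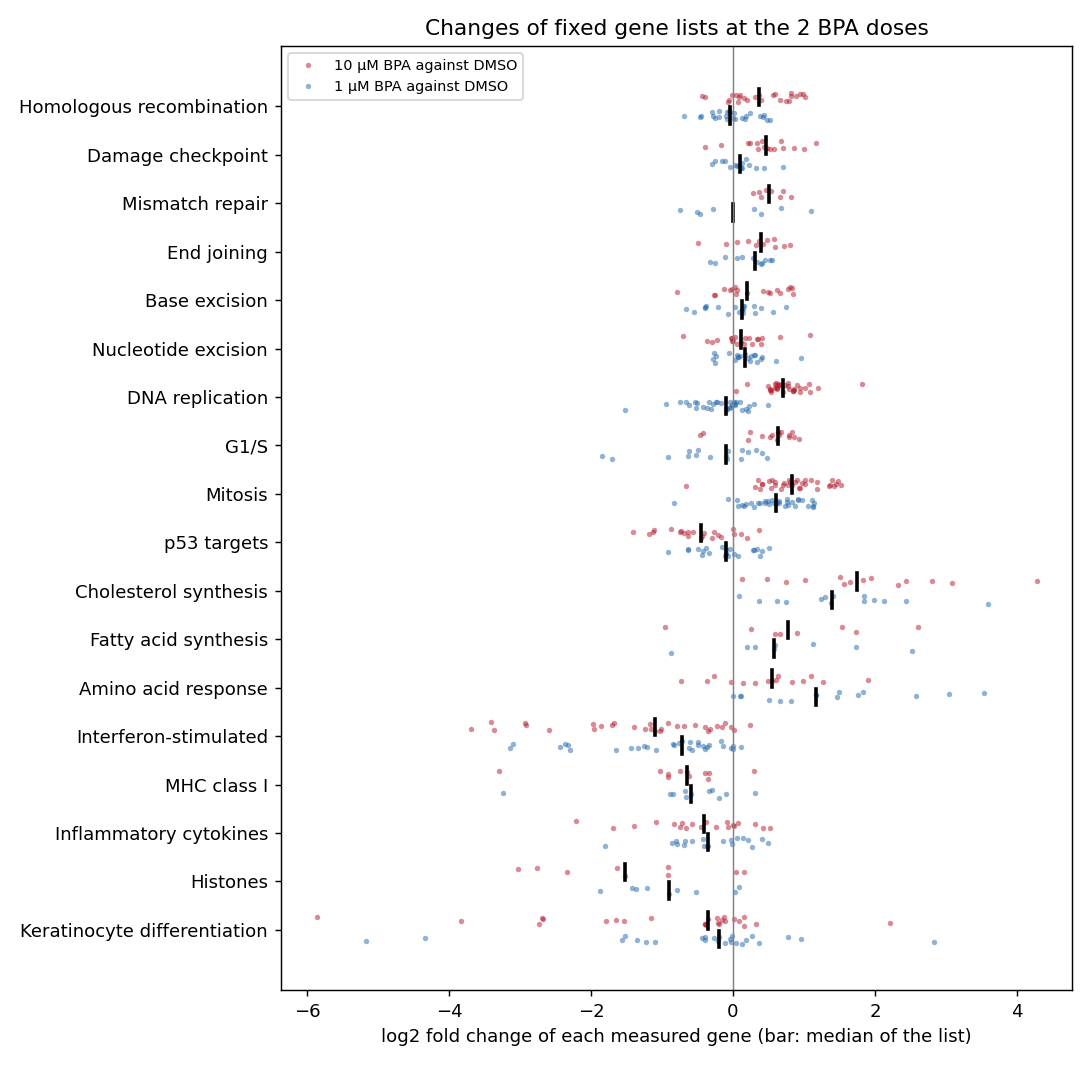
Log2 fold change (horizontal axis) of each measured gene of 18 fixed lists (vertical axis) at 10 µM BPA (red) and 1 µM BPA (blue) against DMSO, with a bar at each list's median. The replication list has a median of 0.70 at 10 µM and -0.10 at 1 µM, while cholesterol synthesis lies at 1.74 and 1.40.

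Cholesterol synthesis had the highest median of the lists at 10 µM. Of 14 cholesterol synthesis genes 13 rose and none fell (median 1.74, adjusted p = 2.39e-15, adjusted p = 0.22 with an estimated correlation), with the sterol sensor INSIG1 up 19.4-fold (4.28 ± 0.09) and HMGCS1, which feeds the pathway, up 8.52-fold (3.09 ± 0.10). Fatty acid synthesis had 6 of 8 higher and 1 lower (median 0.78, adjusted p = 0.000118, adjusted p = 0.22 with an estimated correlation), among them the desaturase SCD at 2.61 and FASN at 1.54. Respiratory chain genes rose in 10 of 22 cases with none lower (median 0.23, adjusted p = 0.000402), and splicing factors in 16 of 24 with 1 lower (median 0.32, adjusted p = 4.95e-05). The list of DNA methylation machinery had 9 of 14 higher and 1 lower (median 0.41, adjusted p = 0.00237), including the oxygenase TET1 at 1.18 and the histone methyltransferase EZH2 at 1.02. With an estimated correlation these last 3 lists had an adjusted p = 0.37, an adjusted p = 0.528 and an adjusted p = 0.341.

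Interferon-stimulated genes fell at 10 µM, 24 of 31 with none higher (median -1.10, adjusted p = 7.1e-17, adjusted p = 0.164 with an estimated correlation). IFIT1, which binds foreign RNA, was at least 12.9-fold lower (-3.69 ± 0.10), to 4.82, and IFI6 10.6-fold lower. The IFIT1 value lay below the lower quartiles of the 10 µM arrays (4.92 and 4.95), near the bottom of the scale. Genes of antigen presentation by MHC class I fell in 10 of 11 cases with 1 higher (median -0.65, adjusted p = 1.18e-05, adjusted p = 0.251 with an estimated correlation), with the immunoproteasome subunit PSMB9 at -3.30 and HLA-B and HLA-C, whose similar sequences may share probes, both at -0.92. Inflammatory genes fell in 11 of 20 cases with 3 higher (median -0.41, adjusted p = 0.00136, adjusted p = 0.352 with an estimated correlation), including the prostaglandin synthase PTGS2 at -2.21 and IL1B at -1.40. Of 9 histone genes 7 fell (median -1.53, adjusted p = 3.91e-06, adjusted p = 0.22 with an estimated correlation), with H2BC5 at -3.03 and H2AC6 at -2.77, members of a family of near-identical copies. Keratinocyte differentiation genes fell in 13 of 25 cases with 2 higher (median -0.35, adjusted p = 1.26e-05, adjusted p = 0.22 with an estimated correlation), among them S100A8 at -2.68 and SPRR1B at -2.73. Epithelial junction genes fell in 9 of 18 cases with 1 higher (median -0.27, adjusted p = 0.00617, adjusted p = 0.251 with an estimated correlation), including the tight junction gene CLDN1 at -1.44.

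The largest single rises at 10 µM were in NLGN4X, a synaptic adhesion gene (5.25 ± 0.18, from 4.38 ± 0.53 to 9.64 ± 0.02; SD, n = 2), the pseudogene ABCA17P (5.19 ± 0.26, with a DMSO SD of 0.80), CEP15 (4.30), INSIG1, the hyaluronan-binding gene TNFAIP6 (3.62), ZNF605 (3.38), NAP1L5 (3.31) and NCR3LG1, a ligand of natural killer cells (3.27). DMSO values of NLGN4X, CEP15 and ZNF605 lay below 4.97, the lower quartile of the DMSO arrays, and the value of PIGR at 10 µM (4.85) below those of the 10 µM arrays, so these folds are lower bounds. The largest falls were in LCN2, an iron-scavenging secreted protein (-5.86 ± 0.11, 58.2-fold lower, from 13.26 ± 0.04 to 7.40 ± 0.18), the plasminogen activator PLAT (-5.39 ± 0.10, 42-fold lower), GABRP (-4.44), the chemokine CXCL6 (-4.30), the complement factor CFB (-4.04), the immunoglobulin transporter PIGR (-4.04), PDZK1IP1 (-3.96) and the keratin KRT13 (-3.83). CFB was called from a probe set ending in _s_at or _x_at, and without such probe sets its value was -0.19 (adjusted p = 0.221).

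Of 11 further genes that the study is known to have examined, 5 rose and 1 fell at 10 µM (median 0.02, adjusted p = 0.199 for the list). Adjusted over the list alone, 5 rose and 2 fell, which is not independent evidence since the study chose them on these samples. CCNA1, a cyclin, rose 3.43-fold (1.78 ± 0.09), the nucleoporin gene NUP98 rose by 0.96, PDCD5 by 0.35, SRSF11 by 0.32 and FOXP1 by 0.28, and PARD6G fell by 0.41. BCL2L11 (0.02), THBS1 (0.01), CDKN2A (-0.27), TNFRSF10C (-0.32) and TNFRSF10D (-0.02) were not called. CDKN2A was called without replicate 2 of the 10 µM group (-0.46, adjusted p = 0.00846) and lay at -0.09 without replicate 1. TNFRSF10C was called without replicate 1 of that group (-0.48, adjusted p = 0.0137) and lay at -0.16 without replicate 2. Without replicate 2 of the DMSO group PDCD5 (adjusted p = 0.0821), SRSF11 (0.144), FOXP1 (0.107) and PARD6G (0.0542) were not called. The first 3 were also not called without replicate 1 of the 10 µM group (0.0633, 0.095 and 0.0713), FOXP1 without replicate 1 of the DMSO group (0.115) and PARD6G without replicate 2 of the 10 µM group (0.0525). THBS1 was at 0.73 (adjusted p = 0.00106) on its probe set without an _x_at or _s_at ending. SRSF11, read in the same way, was at 0.23 and lost its call (adjusted p = 0.142).

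The amino acid response list was called higher at 10 µM (10 of 15 higher, 3 lower, median 0.55, adjusted p = 0.000701), and the matrix protease (2 of 19 higher, 9 lower, median -0.25, adjusted p = 0.0186) and integrin lists (1 of 11 higher, 6 lower, median -0.34, adjusted p = 0.018) lower. The values with an estimated correlation were an adjusted p = 0.22, an adjusted p = 0.258 and an adjusted p = 0.261. The integrin list was not called without replicate 2 of the 10 µM group (adjusted p = 0.0577). Without probe sets ending in _x_at or _s_at neither the matrix protease list (median -0.13, adjusted p = 0.166) nor the integrin list (median -0.29, adjusted p = 0.115) was called. The urokinase gene PLAU fell by 2.49 and the collagen receptor subunit ITGA2 by 1.55. The list of estrogen-responsive genes was not called (7 of 22 higher, 3 lower, median -0.01, mean -0.11 and a test toward higher values with an adjusted p = 0.724), nor was that of receptors reported to bind BPA (2 of 9 higher, adjusted p = 0.646), in which AHR rose by 0.53 and the thyroid hormone receptor THRB by 0.41. Xenobiotic response genes were not called as a list (adjusted p = 0.501), although the sulfotransferase SULT1A1 rose by 1.07 and CYP1A1 fell by 0.72. Neither were the lists of basal (adjusted p = 0.616), luminal (0.418) or mesenchymal genes (0.544), although within them the basal keratin KRT14 rose by 2.01, the luminal keratin KRT8 by 1.06 and TWIST1 by 1.19 while fibronectin (FN1) fell by 1.89. Marker lists of fibroblasts, endothelium, leukocytes, adipocytes and myoepithelium had an adjusted p of 0.204, 0.427, 0.627, 0.762 and 0.555. The remaining lists, which cover further stress, survival and signalling programmes, had an adjusted p from 0.127 to 0.945.

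**Figure D2:**
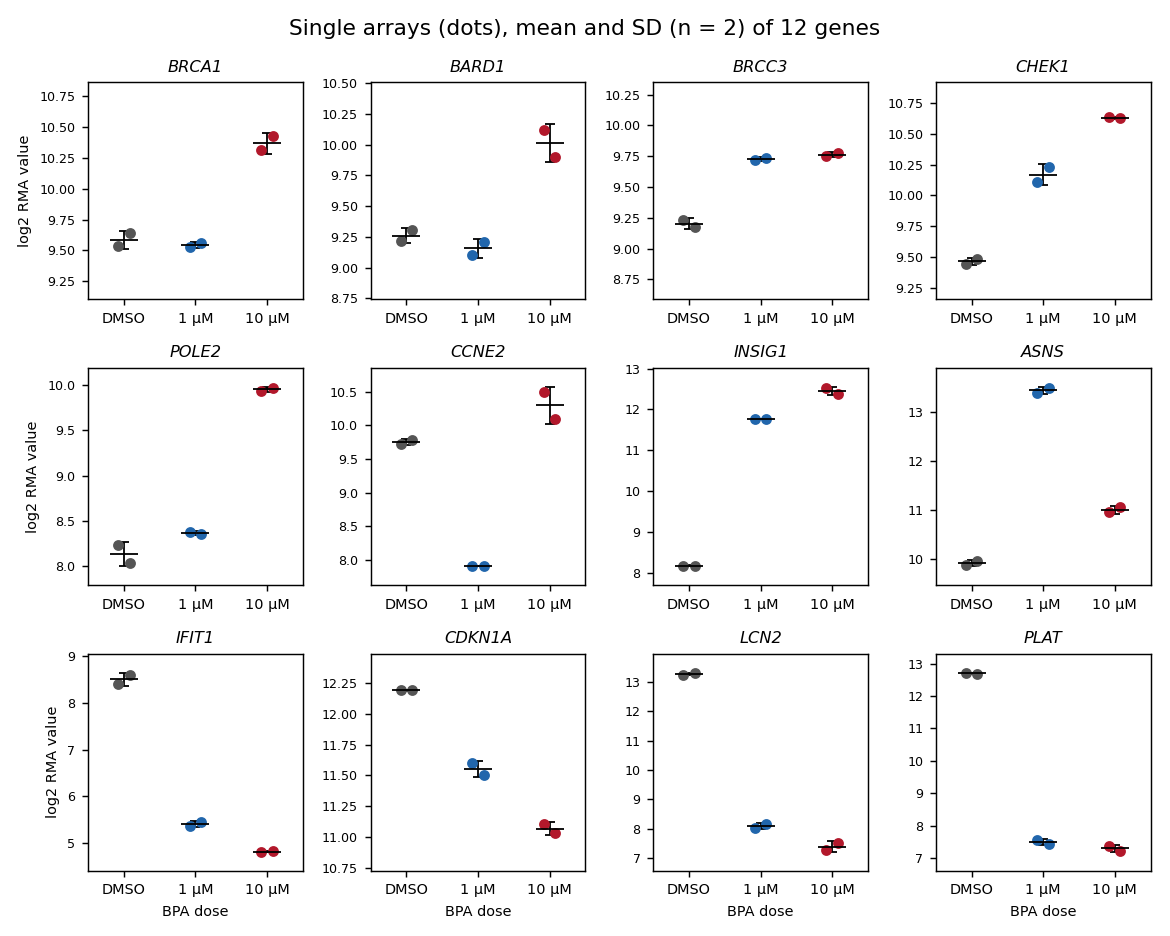
Log2 RMA value (vertical axes) of 12 genes on each array (dots) in DMSO, 1 µM and 10 µM BPA (horizontal axes), with the mean and SD (n = 2) in black. BRCA1 lies at 9.59 in DMSO, 9.54 at 1 µM and 10.37 at 10 µM, and LCN2 at 13.26, 8.10 and 7.40.

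At 1 µM BPA the sterol, interferon and mitosis lists were called in the direction seen at 10 µM (adjusted p = 0.22, 0.164 and 0.241 with an estimated correlation). The repair union was not called. Of 33 replication genes 13 fell, 2 rose and the rest were not called (adjusted p = 0.56 for the list with an estimated correlation). Of 15 amino acid response genes 12 rose (adjusted p = 0.164 with an estimated correlation), among them the cystine transporter SLC7A11, 8.21-fold. In all, 5310 of 19775 genes were called, 3087 higher and 2223 lower, and 627 changed at least 2-fold (314 higher, 313 lower). The share of higher genes was 58.1%, 50.8% after repeated quantile normalization and 66.8% with equal array medians. Without replicate 1 or replicate 2 of the 1 µM group 3484 and 3102 genes were called.

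Of 119 repair genes 36 rose and 18 fell at 1 µM (median 0.11, adjusted p = 0.0605, adjusted p = 0.677 with an estimated correlation). Adjusted over the list alone, 40 rose and 21 fell. Its adjusted p was 0.0128 with the mean of all probe sets of each gene, 0.0481 without either 10 µM array, 0.0472 without replicate 1 of the 1 µM group and 0.125 without replicate 2. After repeated quantile normalization the adjusted p was 0.383 and the median fell to 0.048. BRCA1 (-0.04 ± 0.09, adjusted p = 0.783) and BARD1 (-0.10 ± 0.10, adjusted p = 0.524) were not called, and BRCC3 rose by 0.52 ± 0.09 (adjusted p = 0.00101). As a list these 3 were not called (adjusted p = 0.636), with a median of -0.04 and a mean of 0.13. Mismatch repair split, with 4 of 8 genes higher and 4 lower (adjusted p = 0.933): MSH3 rose by 0.67, while MSH6 fell by 0.75 and PCNA by 0.51. Nucleotide excision repair (7 of 21 higher, none lower, median 0.18, adjusted p = 0.0457) and translesion synthesis (5 of 12 higher, 1 lower, median 0.21, adjusted p = 0.0381) were called, with the damage recognition gene XPA at 0.96 and the polymerase POLI at 0.94. Estimating the correlation gave an adjusted p = 0.352 and an adjusted p = 0.603. Both calls were lost among the more highly expressed genes (medians 0.18 and 0.17, adjusted p = 0.322 and 0.307), after repeated quantile normalization (medians 0.08 and 0.13, adjusted p = 0.287 and 0.0931) and without replicate 1 of the DMSO group (adjusted p = 0.0693 and 0.0855). The nucleotide excision call was also lost without replicate 2 of the DMSO group (adjusted p = 0.0795), without replicate 1 or 2 of the 1 µM group (0.0566 and 0.06) and with the replicate number as a block (0.0559), and the translesion call with the mean of all probe sets (0.0504). Homologous recombination, Fanconi, base excision, end joining and checkpoint lists had an adjusted p of 0.973, 0.925, 0.812, 0.0871 and 0.332, though CHEK1 rose by 0.71.

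Replication genes fell in 13 of 33 cases at 1 µM with 2 higher (median -0.10, adjusted p = 0.0136, adjusted p = 0.56 with an estimated correlation), including DTL, which targets replication factors for degradation, at -1.52, and the helicase subunit GINS1 at -0.74. G1/S genes fell in 8 of 17 cases with 2 higher (median -0.10, adjusted p = 0.0331, adjusted p = 0.428 with an estimated correlation), with the G1/S cyclins CCNE1 at -1.71 and CCNE2 at -1.84. Mitosis genes rose in 26 of 35 cases with 1 lower (median 0.61, adjusted p = 7.76e-13, adjusted p = 0.241 with an estimated correlation), including the kinetochore genes CENPE at 1.12 and NUF2 at 1.13. The replication call was lost without probe sets ending in _x_at or _s_at (median -0.07, adjusted p = 0.115), and the G1/S call without either 10 µM array (median unchanged, adjusted p = 0.0565) and when only the compared groups were fitted (adjusted p = 0.0588).

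Amino acid response genes rose in 12 of 15 cases at 1 µM with none lower (median 1.17, adjusted p = 1.29e-12, adjusted p = 0.164 with an estimated correlation). SLC7A11 rose by 3.04 ± 0.09, the pseudokinase gene TRIB3 by 2.58 and the serine synthesis gene PHGDH by 1.84. ASNS rose by 3.53 ± 0.09 on a probe set ending in _s_at, and its value without such probe sets was 0.09 (adjusted p = 0.535). The unfolded protein response list was also higher (7 of 16 higher, 1 lower, median 0.17, adjusted p = 0.0102, adjusted p = 0.251 with an estimated correlation), with the transcription factor XBP1 at 0.94. This call was lost among the more highly expressed genes (median 0.17, adjusted p = 0.155) and after repeated quantile normalization (median 0.08, adjusted p = 0.0521).

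Cholesterol synthesis genes rose in 13 of 14 cases at 1 µM (median 1.40, adjusted p = 1.18e-14, adjusted p = 0.22 with an estimated correlation), with INSIG1 up 12.1-fold and HMGCS1 4.36-fold. Fatty acid synthesis (6 of 8 higher, 1 lower, median 0.58, adjusted p = 0.000466) and the respiratory chain (13 of 22 higher, none lower, median 0.34, adjusted p = 8.07e-06) also rose, with SCD at 2.52 and the cytochrome gene CYC1 at 0.62. The values with an estimated correlation were an adjusted p = 0.22 and an adjusted p = 0.318. Interferon-stimulated genes fell in 24 of 31 cases with none higher (median -0.72, adjusted p = 4.3e-16, adjusted p = 0.164 with an estimated correlation), IFIT1 by 3.10. MHC class I genes (8 of 11 lower, 1 higher, median -0.60, adjusted p = 5.96e-05), histones (7 of 9 lower, median -0.90, adjusted p = 1.18e-05), inflammatory genes (10 of 20 lower, 3 higher, median -0.36, adjusted p = 0.00945) and keratinocyte differentiation genes (11 of 25 lower, 4 higher, median -0.20, adjusted p = 0.0119) were lower. Estimating the correlation gave an adjusted p = 0.251, 0.22, 0.406 and 0.251. PSMB9 fell by 3.25 and H2BC5 by 1.87, while the protease KLK5 rose by 2.83. The MHC class I and fatty acid calls were lost without probe sets ending in _x_at or _s_at (medians -0.20 and 0.58, adjusted p = 0.248 and 0.0573).

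The largest rises at 1 µM were in the monocarboxylate transporter family gene SLC16A4 (4.88 ± 0.09, 29.4-fold), NLGN4X (4.56), TNFAIP6 (4.18), CEP15 (4.09), ABCA17P (4.02), INSIG1 (3.59), the selenium carrier SELENOP (3.55) and ASNS. The largest falls were in PLAT (-5.19 ± 0.10, 36.6-fold lower), LCN2 (-5.16 ± 0.11, 35.8-fold lower), KRT13 (-4.34), PIGR (-3.95), COXFA4L3 (-3.95), the adhesion molecule CEACAM6 (-3.80), the microtubule gene MAP1B (-3.74) and RAB38 (-3.71). The DMSO values of NLGN4X and CEP15 lay below the lower quartile of their arrays, and the 1 µM value of PIGR (4.93) at that of its arrays, so these folds are lower bounds and their order is uncertain. SELENOP was measured by a probe set ending in _s_at and its value without such probe sets was 0.07 (adjusted p = 0.769).

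Of the 11 further genes from the study, 4 rose and 2 fell at 1 µM (median 0.16, adjusted p = 0.0922 for the list), and 5 rose and 2 fell adjusted over the list alone, with the same reservation as at 10 µM. CCNA1 rose 7.03-fold (2.81 ± 0.09), NUP98 by 1.09, BCL2L11, which promotes apoptosis, by 0.66 and the decoy receptor gene TNFRSF10D by 0.59. PARD6G fell by 0.60 and THBS1 by 0.37, and THBS1 was not called without replicate 1 or 2 of the DMSO group (adjusted p = 0.0883 and 0.172) or of the 1 µM group (0.0948 and 0.262). On its probe set without an _x_at or _s_at ending THBS1 was at -0.01 (adjusted p = 0.956). FOXP1 (0.22), PDCD5 (0.14), SRSF11 (0.16), CDKN2A (-0.22) and TNFRSF10C (-0.18) were not called.

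Smaller shifts at 1 µM were called for heat shock genes (none of 9 higher, 4 lower, median -0.23, adjusted p = 0.018), matrix proteases (2 of 19 higher, 8 lower, median -0.22, adjusted p = 0.0136), integrins (1 of 11 higher, 3 lower, median -0.24, adjusted p = 0.0381), TGF-beta targets (3 of 17 higher, 7 lower, median -0.18, adjusted p = 0.0248), Wnt targets (none of 13 higher, 4 lower, median -0.25, adjusted p = 0.0382), myoepithelial markers (none of 7 higher, 3 lower, median -0.15, adjusted p = 0.0266) and splicing factors (3 of 24 higher, median 0.15, adjusted p = 0.0402). The values with an estimated correlation were an adjusted p = 0.352, 0.255, 0.313, 0.408, 0.403, 0.354 and 0.685. PLAU fell by 2.60, the growth factor TGFB2 by 3.10 and the activin subunit INHBA by 1.64. Without probe sets ending in _x_at or _s_at the heat shock (adjusted p = 0.0734), matrix protease (0.115), integrin (0.19) and splicing calls (0.0833) were lost, with medians of -0.33, -0.16, -0.24 and 0.13. The myoepithelial and integrin calls were lost without replicate 2 of the 1 µM group, where their medians were -0.08 and -0.16. The Wnt call was lost without replicate 1 of the 1 µM group (median -0.25) or of the DMSO group (median -0.12). Integrins also lost their call with the mean of all probe sets (adjusted p = 0.0893) and without replicate 2 of the DMSO group (adjusted p = 0.0524). Splicing factors lost theirs among the more highly expressed genes (median unchanged at 0.15, adjusted p = 0.322) and after repeated quantile normalization (median 0.08, adjusted p = 0.224). That call was also lost without replicate 2 of the DMSO group (median 0.147) or replicate 1 or 2 of the 1 µM group (0.149 and 0.144). Targets of p53 were not called (6 of 23 higher, 8 lower, adjusted p = 0.256), though CDKN1A fell by 0.64. Lists of estrogen-responsive genes, receptors for BPA and xenobiotic response had an adjusted p of 0.555, 0.151 and 0.724, and the marker lists of fibroblasts, endothelium, leukocytes and adipocytes 0.127, 0.533, 0.366 and 0.948. The remaining lists had an adjusted p from 0.07 to 0.968.

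Between the doses, replication and G1/S genes stood higher at 10 µM and amino acid response genes higher at 1 µM. In this direct comparison 2479 genes were called, 1182 higher at 10 µM and 1297 lower, of which 191 differed at least 2-fold (103 higher, 88 lower). Of 33 replication genes 31 were higher at 10 µM and none lower (median 0.94, adjusted p = 6.36e-40, adjusted p = 0.22 with an estimated correlation), with DTL at 2.05 and POLE2 at 1.59. Of 17 G1/S genes 16 were higher (median 0.70, adjusted p = 4.23e-20, adjusted p = 0.22 with an estimated correlation), with CCNE2 at 2.38 ± 0.12 and CCNE1 at 1.28. Of 15 amino acid response genes 13 were lower at 10 µM and none higher (median -0.79, adjusted p = 3.2e-14, adjusted p = 0.164 with an estimated correlation), with SLC7A11 at -1.13 and TRIB3 at -1.31. Without replicate 1 or replicate 2 of the 1 µM group the direct comparison called 1151 and 1050 genes.

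The repair union was higher at 10 µM than at 1 µM, with 37 of 119 genes higher and 8 lower (median 0.16, adjusted p = 3.69e-08, adjusted p = 0.354 with an estimated correlation). Adjusted over the list alone, 47 were higher and 12 lower. Homologous recombination (11 of 25 higher, 1 lower, median 0.28, adjusted p = 8.55e-08), checkpoint (11 of 16 higher, 1 lower, median 0.41, adjusted p = 9.98e-08), mismatch (5 of 8 higher, 1 lower, median 0.49, adjusted p = 0.00136), Fanconi (4 of 12 higher, 1 lower, median 0.20, adjusted p = 0.00449) and base excision repair (6 of 19 higher, none lower, median 0.14, adjusted p = 0.00273) were called. With an estimated correlation these had an adjusted p = 0.341, 0.257, 0.313, 0.251 and 0.261. The Fanconi call was lost without probe sets ending in _x_at or _s_at (median 0.07, adjusted p = 0.0781) and among the more highly expressed genes (adjusted p = 0.0693), and the base excision call without such probe sets (adjusted p = 0.103). EXO1, a nuclease of several repair pathways, was higher by 1.28, the flap endonuclease FEN1 by 1.29, MSH6 by 1.14 and PCNA by 1.04. End joining (adjusted p = 0.127), translesion synthesis (0.241) and nucleotide excision (0.544) were not called. Of the study's own repair genes 2 of 3 were higher at 10 µM (adjusted p = 0.00376, adjusted p = 0.251 with an estimated correlation), again chosen by the study on these samples.

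Other lists higher at 10 µM were mitosis (11 of 35 higher, median 0.23, adjusted p = 1.58e-09), cholesterol synthesis (7 of 14, median 0.37, adjusted p = 5.82e-06), glycolysis and hypoxia genes (8 of 17, median 0.30, adjusted p = 8.07e-06), heat shock (4 of 9, median 0.23, adjusted p = 0.00945), splicing factors (4 of 24, median 0.19, adjusted p = 0.000813) and the DNA methylation machinery (6 of 14 higher, 1 lower, median 0.14, adjusted p = 0.00324). Lists lower at 10 µM were p53 targets (10 of 23 lower, median -0.31, adjusted p = 2.41e-08), the unfolded protein response (9 of 16 lower, 1 higher, median -0.44, adjusted p = 0.000118), keratinocyte differentiation (11 of 25 lower, 1 higher, median -0.20, adjusted p = 1.18e-05), histones (6 of 9 lower, median -0.43, adjusted p = 5.87e-05), epithelial junctions (5 of 18 lower, median -0.26, adjusted p = 0.00031), interferon-stimulated genes (10 of 31 lower, 2 higher, median -0.15, adjusted p = 0.000806) and metallothioneins (1 of 8 lower, median -0.21, adjusted p = 0.018). With an estimated correlation these 13 lists had an adjusted p from 0.22 to 0.576. The glycolytic regulator PFKFB3 stood higher at 10 µM by 1.21, and the stress sensor SESN2 lower at -1.24, SPRR1B at -1.63 and the antiviral gene IFIT2 at -1.84. The splicing call was lost without replicate 1 of the 10 µM group, where the median fell to 0.099. The metallothionein call was lost without probe sets ending in _x_at or _s_at (median -0.12, adjusted p = 0.582). It was also lost without replicate 1 of the 10 µM group (median -0.13) or of the 1 µM group (median -0.16).

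The genes furthest apart between the doses were, on the higher side at 10 µM, the neuronal RNA-binding gene ELAVL2 (3.37 ± 0.11, 10.3-fold), the lipase LPL (3.30), PABPC4L (2.67), the desaturase SCD5 (2.67) and CCNE2. SCD5 stood at 8.78 ± 0.12 in DMSO, 8.78 ± 0.26 at 10 µM and 6.11 ± 0.22 at 1 µM (SD, n = 2). On the lower side were the cysteine synthesis gene CTH (-2.84 ± 0.11, 7.16-fold), ACSS3 (-2.70), the non-coding LINC02806 (-2.65), ASNS (-2.44) and BEX2 (-2.22). ELAVL2 rose by 2.22 at 10 µM and fell by 1.15 at 1 µM, and KRT14 was higher at 10 µM than at 1 µM by 2.16. Without probe sets ending in _x_at or _s_at the ASNS value was -0.02 (adjusted p = 0.934).

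**Figure D3:**
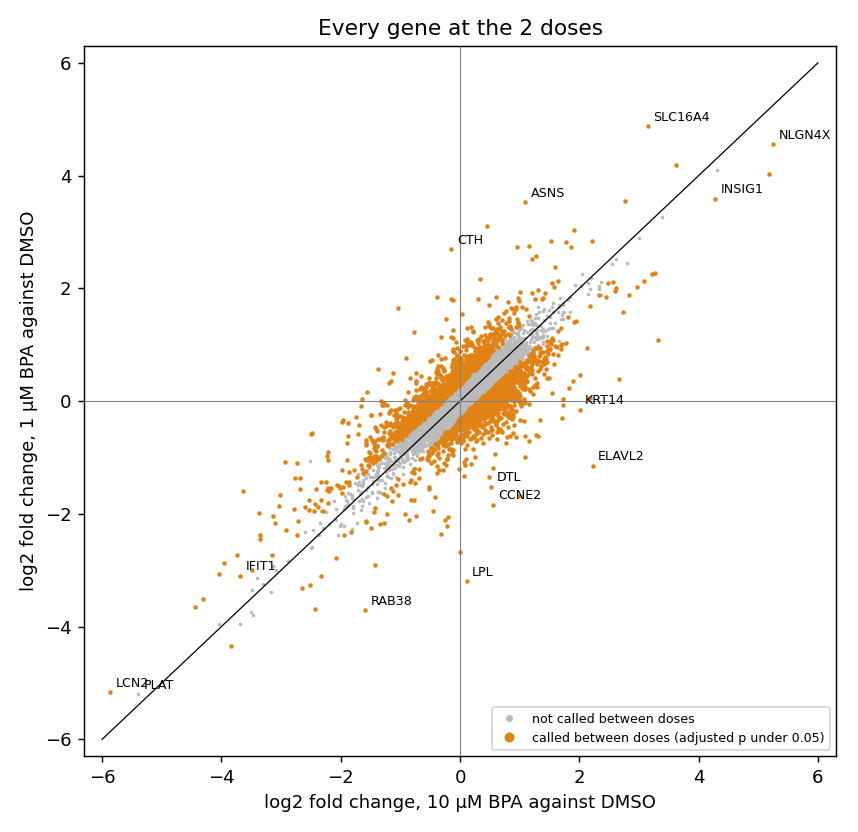
Log2 fold change against DMSO of each gene at 10 µM (horizontal axis) and 1 µM BPA (vertical axis), with genes called between the doses in orange, the rest in grey, and the line of equal change. The doses correlate at r = 0.81 across genes, and ASNS, CTH, LPL, CCNE2 and ELAVL2 lie far from the line.

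Both doses changed many of the same genes in the same direction. Across 19775 genes, which are not independent replicates, the log2 changes of the doses correlated at r = 0.81 (Spearman's rho 0.74), against r = 0.50 in 100 simulations of unchanged groups that share the 2 DMSO arrays. With a separate DMSO array for each dose, a comparison added after the data were seen, r was 0.755 and 0.761 for the 2 ways of dealing out the arrays. The covariance was 0.157 against a simulated 0.00551, a difference of 0.152. At both doses 2173 genes were higher, against 533 for independent lists, and 1564 were lower, against 311. Unchanged groups shared a mean of 0.07 calls, but they hold no changed gene and so give few calls by construction. The counts for independent lists leave out the shared DMSO arrays. Neither value shows how much of the overlap in calls the shared arrays add. Among 409 genes changed at least 2-fold in the same direction at both doses, 63.1% had the larger change at 10 µM. Their median ratio of the 1 µM to the 10 µM change was 0.94, and 155 of them differed between the doses by the direct test. The 2-fold bound leaves out genes that changed strongly at a single dose only, which draws the ratio toward 1. The ratio is therefore no measure of how dose alters the size of the changes. In opposite directions 109 genes were called.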

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

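The tests of the shared DMSO arrays, including separate arrays for each dose, and of selection were chosen after the results were seen, and so was the median difference of 0.4 above which lists are given here. The doses differed by a direct test in 2479 genes, and 109 genes were called against DMSO in opposite directions at the 2 doses, which is the difference between groups that brings them here. ZNF367 (1.09 at 10 µM and -0.99 at 1 µM), the chromatin remodeller HELLS (1.09 and -0.62) and the transcription factor MYB (0.95 and -0.64) are examples. The labels do not say that the arrays of a dose came from separate cultures. A difference in recovery, passage or handling between the cultures of the 2 doses cannot be told apart from dose. Between the doses 15 lists were called higher and 8 lower at 10 µM with the preset correlation and none with an estimated correlation (lowest adjusted p = 0.164). Of these, 8 had a median difference above 0.4 in size. One is the study's own repair list, with a median of 0.83 over 3 genes, which the study chose on these samples. Replication, G1/S, mismatch repair and checkpoint genes were higher at 10 µM, with medians of 0.94, 0.70, 0.49 and 0.41, and amino acid response, unfolded protein response and histone genes were lower, with medians of -0.79, -0.44 and -0.43. A signal also appears in probe sets that the comparisons above do not use. Of 13522 probe sets without a single gene symbol, 1672 were called at 10 µM (251 at least 2-fold) and 1287 at 1 µM (194 at least 2-fold).

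The rise of the repair list at 10 µM (median 0.33 ± 0.05, SE over members) was set beside the cell cycle. The 85 genes of the 3 cell cycle lists rose more, with a median of 0.71 ± 0.05. Another set held 49 repair genes from the base excision, nucleotide excision and end joining lists. Members of the cell cycle, homologous recombination and Fanconi lists were left out of it. Its median was 0.19 ± 0.10, with 20 higher and 5 lower. It still includes RPA1 and RPA3, while RPA2 was left out as a member of the replication list. Only LIG1, PCNA, FEN1 and RPA2 of the repair list are also in the cell cycle lists. Without them the repair median was 0.31 (adjusted p = 1.15e-08). Removing so few of 119 genes could hardly move the median, so this does not separate the rise from the cell cycle. A larger share of cycling cells could still lie behind part or all of the rise. It cannot be told apart from a response of repair genes. The median of the 49 genes was not within 1 SE of 0, the bound set beforehand for the cell cycle alone. That bound is weak, since the more highly expressed genes as a whole had a median of 0.07. Whether the 49 genes partly follow the cycle themselves was not tested. The cell cycle genes rose by more than the repair genes, so the bound that would argue against the cell cycle was not met. At 1 µM the cell cycle median was 0.106 ± 0.07 beside a repair median of 0.11 ± 0.03. The 49 genes had a median of 0.14 ± 0.05 (17 higher, 5 lower), so the bound for the cell cycle alone was again not met. The question stays open there because the more highly expressed genes as a whole had a median of 0.07, the cell cycle lists go both ways and the repair list was not called. The wider spread of values on replicate 1 of the 10 µM group was argued against as the whole cause of the rise, since the smallest share of the median kept after quantile normalization or without that array was 0.756, only just above the bound of 0.75 set beforehand. A smaller contribution stays open.

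The changes shared by both doses were larger than the shared DMSO arrays give by chance: their covariance was 28.5 times the one simulated from the spread between replicates, and with a separate DMSO array for each dose 96% and 96.5% of it remained. A trend with gene length was argued against as well, since 0.993 of the covariance was kept after a fit on log gene length. Selection in the invasion assay and the later passages may also produce changes common to both doses. Among genes changed at least 2-fold at both doses, the median ratio of the 1 µM to the 10 µM change was 0.938. That filter draws the ratio toward 1. The ratio cannot separate selection from the compound either. The design puts every BPA array on one side and the labels do not say which cells were arrayed. The tests of the shared DMSO arrays rest on the spread between replicate arrays, which may be technical. A deviation common to both DMSO arrays, from handling or from a single culture, was not tested and stays open.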

How the results depend on the processing

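The crossed replicate block and the separate DMSO array for each dose were chosen after the data were seen, and the other alternatives before. Of 4478 repeats of results for named genes under the alternatives, 4288 kept direction and side of the threshold (95.8%), 143 fell below it, 24 came to pass it and 23 changed sign. Several alternatives, such as the block and the fit to the compared groups, leave every log2 change as it was. Apart from the study's own genes, the named genes were also chosen largely for size or p in these data. The pooled share therefore overstates how stable the values are. Among all called genes, the mean of all probe sets kept call and direction for 4957 of 6178 at 10 µM. It kept them for 4028 of 5310 at 1 µM and 1806 of 2479 between doses. Without probe sets ending in _x_at or _s_at, 216 of 253 repeats kept direction and side of the threshold, and 12 changed sign. The counts of genes called stayed within 1.5 times of those reported under every alternative except these. With a 2-fold change required as well they were 762 (10 µM), 627 (1 µM) and 191 (between doses). Leaving out 1 array gave 3102 to 5955 at 1 µM and 1050 to 2532 between doses, where the lone array left in a group is assumed to vary like the others and fewer arrays lower the power. With a separate DMSO array for each dose the correlation of the doses was 0.755 and 0.761, where each dose has a single control. Leaving out 1 array it ran from 0.792 to 0.819 and the repair median at 1 µM from 0.0854 to 0.136. Repeated quantile normalization moved that repair median further, to 0.0484. The share of called genes that were higher depended on scaling: 55.3% at 10 µM and 58.1% at 1 µM as reported, 48.4% and 50.8% after repeated quantile normalization and 63.1% and 66.8% with equal array medians. The repair list stayed called at 10 µM except with an estimated correlation (median 0.33, adjusted p = 0.344). At 1 µM it came to be called when only the compared groups were fitted (0.11, adjusted p = 0.0495) and with the mean of all probe sets (0.0855, adjusted p = 0.0128). Without LIG1, PCNA, FEN1 and RPA2 it was called as well, with an unchanged median (0.11, adjusted p = 0.0405). The cause was not tested.

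Sign changes, all but that of SRSF7 without a call, were as follows. After repeated quantile normalization BCL2L11 (-0.0829) and THBS1 (-0.10) changed at 10 µM. With equal array medians TNFRSF10D changed at 10 µM (0.0304) and BRCA1 at 1 µM (0.00561). With the mean of probe sets BCL2L11 at 10 µM (-0.0118) and THBS1 at 1 µM (0.0434) did. Without probe sets ending in _x_at or _s_at the changes at 10 µM were TNFRSF10C 0.0589, FANCM -0.0298, FANCC -0.0899, IDI1 -0.0629, IL1A 0.16 and SRSF7 -0.51 (adjusted p = 0.00116). At 1 µM they were SRSF11 -0.29, TNFRSF10C 0.19, UBE2B -0.16, CENPF -0.0210, CDC25C -0.0339 and IDI1 -0.0982. These genes were then read from another probe set, and why the probe sets differ was not tested. Leaving out arrays gave -0.17 to 0.19 for THBS1 and -0.106 to 0.0749 for TNFRSF10D at 10 µM, and -0.0957 to 0.00741 for BRCA1 at 1 µM.

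With the replicate number as a block (replicate block), 5864, 4960 and 2190 genes were called at 10 µM, at 1 µM and between doses, and the repair list had an adjusted p of 1.79e-09 and 0.0674. This block ended the call of nucleotide excision repair at 1 µM (adjusted p = 0.0559). The deviations of equally numbered replicates correlated at -0.109, -0.0362 and -0.0361 between groups, so the numbers showed no pairing. With the numbers crossed in the 10 µM group, in a fit to the DMSO and 10 µM arrays alone, 6656 genes were called. Without a block the fit to these 2 groups called 5440. Why the crossed count was higher was not tested. Signal over background limits the fold changes of genes near the bottom of the scale, since RMA values carry no detection call.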

Other observations

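Single genes of the fixed lists are given here as values, although the mesenchymal list (adjusted p = 0.544 at 10 µM and 0.441 at 1 µM) and the fibroblast marker list (0.204 and 0.127) were not called. Periostin (POSTN), a matrix protein, fell, with changes of -2.65 ± 0.11 at 10 µM and -3.32 ± 0.11 at 1 µM (SE, n = 2 arrays per group), fibronectin (FN1) by 1.89 and 1.78, and the TGF-beta feedback gene PMEPA1 by 1.64 and 1.85. The transcription factor SNAI2 fell by 1.39 and 1.13 while TWIST1 rose by 1.19 and 1.08. PECAM1, an adhesion molecule of endothelium, rose by 1.38 and 1.81, while CDH5, a cadherin of the same cell type, fell by 0.47 and 0.53. The ferritin light chain gene FTL fell by 1.20 and 1.09.

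Genes that promote apoptosis went both ways. At 10 µM 3 of 21 rose and 8 fell (adjusted p = 0.183 for the list), with PMAIP1 at -1.11 ± 0.13 and BAX at -0.74 ± 0.10, and of 8 genes that oppose it 3 fell (adjusted p = 0.256), BCL2L1 by 0.56. At 1 µM HRK rose by 0.74 and BIK fell by 0.77. The growth factor receptor EGFR fell by 1.05 at 1 µM.

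The test of neighbouring genes and its bound were chosen after the values were seen. Gains or losses of chromosome segments in the BPA cells could shift neighbouring genes together. Of 236 windows of 40 neighbouring genes, the highest median at 10 µM was 0.377, on chromosome 13, and 0.31 at 1 µM on the same chromosome. These values lay below 0.383 at 10 µM and 0.343 at 1 µM, upper percentiles of the highest medians in 1000 random orders. No window reached 0.585, the shift for a gain of 1 copy of 2 in all cells. The bound set for a partial gain, 0.292, was exceeded by 6 windows at 10 µM and 3 at 1 µM. That bound lies below the limits of the random orders, which none of these windows passed, so they do not show a gain. The lowest medians, -0.222 and -0.213 on chromosome 19, lay below a lower percentile of the lowest medians in the random orders (-0.209 and -0.177). Between the doses the highest median, 0.188 on chromosome X, and the lowest, -0.183 on chromosome 2, also lay beyond such percentiles (0.164 and -0.182). A gain in part of the cells cannot be told apart from a coordinated change in expression, because the arrays measure RNA alone.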
